A study of Mus musculus with 12 samples.

How the data were processed

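Gene expression was measured with 1-colour Agilent microarrays in bone marrow-derived macrophages from mice with (ERRα+/+) or without (ERRα-/-) the nuclear receptor ERRα, encoded by Esrra. Per the labels, the cells came from male C57BL6 mice aged 6 to 8 weeks, were grown for 5 to 7 days in M-CSF, and received either PBS as the solvent or lipopolysaccharide (LPS) at 100 ng/mL. The length of the LPS treatment is not given in the sources used here. The 12 arrays made 4 groups of 3 replicates, taken from the sample labels. Per the labels' protocols, total RNA was extracted with Trizol and labelled with Cy3 by the Low Input Quick Amp kit.

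Per the file headers, the deposited intensity values were made with Agilent Feature Extraction 11.5.1.1 on 1 array design, whereas the submitters' processing notes name version 9.3.2.1. The labels give a smaller array format (4 arrays per slide) for replicate 1 than for replicates 2 and 3 (8 per slide), but every file held 62976 spots of the same design. Per the file headers, the processed signal intensity had been background-subtracted and detrended within each array, with no normalization between arrays. The median signal intensity of the spot and of its local background were deposited as raw values. The other columns used, per the file headers, were flags of 0 or 1 for spots well above background, saturated or non-uniform. The authors' deposited table of intensity values equalled the processed signal at all 62976 spots of every array, so it served as an alternative that moved no value.

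Control spots were removed, which left 59305 spots and 55681 probes per array, and spots of the same probe were averaged. The log2 processed signal minus the array's 75th percentile was analysed. Probes were named through their transcript accession and a RefSeq gene table of the mouse assembly, and 27509 probes named 20887 genes. The other 28172 probes had no gene name and were kept out of the comparisons; 1641 of them carried a RefSeq accession missing there. No columns of other samples were present. A probe was kept when it was well above background on all 3 arrays of at least 1 group, and each gene was represented by its probe with the highest mean level, which left 13113 genes. Values are log2 differences ± the standard error of the model (SE), with n = 3 arrays per group unless stated.

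The signal limits what could be measured: 46.3% to 57.4% of probes per array were well above background, the 75th percentile of the processed signal lay between 340 and 701, and no spot was saturated. The coefficient of variation between spots of the same probe was 3.68% to 4.59% on 10 arrays, but 12.4% on ERRα+/+ PBS replicate 2 and 8.12% on ERRα+/+ PBS replicate 3. Where a group's arrays were not well above background, a fold change is given as a lower bound, computed against the lowest level of a well-above-background probe on each of its arrays. Arrays give no counts, so their number limits the precision.

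Differences were tested with limma 3.58.1 in R 4.3.3 (files read with its data.table package, version 1.17.8), with 1 mean per group, empirical Bayes moderation and the Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The 6 contrasts were LPS against PBS in each genotype, ERRα-/- against ERRα+/+ under PBS, under LPS and averaged over both, and the difference of the LPS response between genotypes. All adjusted p-values of single genes come from limma. In 27 gene lists, camera (limma) tested the members against all other genes with a preset inter-gene correlation of 0.01. The p-values were adjusted over the 162 list tests, and the test was repeated with an estimated correlation. That repeat called 0 of the 162 tests, even where all measured members of a list rose with LPS. A miss with it thus does not weigh against a particular list. The fry test asked whether a list's genes moved, on balance, one way.

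The lists were NF-kB-dependent cytokines and chemokines, inflammatory effectors and receptors, negative feedback on NF-kB and TLR signalling, interferon-stimulated genes, oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid oxidation, mitochondrial ribosome and translation, glycolysis, ERR family with coactivators and direct targets, autophagy and lysosome, alternative activation, cell cycle, cholesterol biosynthesis with LXR targets, MHC class II presentation, oxidative stress response, unfolded protein and heat stress response, apoptosis with p53 targets, and the genes neighbouring Esrra. Cell type lists covered macrophage identity, neutrophils, dendritic cells, B and T lymphocytes with NK cells, mast cells and basophils, erythroid cells and megakaryocytes, stromal cells with fibroblasts and endothelium, and osteoclasts. Strain and sex check genes were listed apart. Of 681 list entries, 669 were on the array.

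The groups, contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined. Named were Esrra, Tnfaip3, Tnf, Il6, Il1b and Nos2 whatever their values; the 5 largest rises and 5 largest falls among called genes whose arrays separated fully between groups and which were well above background in the higher group; and up to 4 members per list with the smallest p. Where 5 or fewer members of a list were called, any could be named. Named members of the lists were therefore selected by their p within these arrays. A few genes that the rule takes are not reported here.

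Replicate 1 of every group was hybridized and scanned on slide 1, and replicates 2 and 3 of every group on slide 2. With all 12 arrays, slide and group were therefore not confounded. Leaving out a replicate 1 array takes its group off slide 1, so that slide and group are then mixed. Deviations of same-numbered arrays from their group means were correlated across genes in all 18 pairs, with r between 0.144 and 0.783 (median 0.304). The labels give only the numbers and state no pairing. Replicates 2 and 3 shared a slide, and the 12 pairs of a number 2 with a number 3 had r between 0.129 and 0.555. In all, 11 of 12 arrays correlated best with an array of their own number, but number 1 was alone on its slide. ERRα-/- PBS replicate 2 had r 0.44 with ERRα+/+ PBS replicate 2 and 0.466 with replicate 3. The arrays thus grouped by slide, and pairing by number within slide 2 stays open. Nothing in the sources used here says whether replicates were separate animals or cultures. Over 188 probes printed at least 8 times, replicates 2 and 3 of a group differed by 2.21 to 4.77 times the spread expected from spots, and replicate 1 differed from them by 11.1 to 28.1 times. Repeat hybridizations of 1 RNA can also differ by more than spots do, so this does not show that the 3 were separate samples. They were counted as such because the labels number them as replicates. The p-values measure only the spread between these arrays, which may be technical.

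Alternatives fixed beforehand were normexp background correction (offset 50, on median signals, since the mean signal column named in the plan was absent), quantile normalization, median centring, no filter on dim probes, a filter on all 12 arrays, the mean of a gene's probes, a trend and robust moderation, array weights, slide as a block, replicate number as a block, slide 2 alone, only the groups compared, an added fold threshold of 1 on the log2 scale, and leaving out each array. Chosen after seeing the data were replicates 2 and 3 averaged into 1 sample (with and without a slide block), leaving out both ERRα+/+ PBS arrays with noisy spots, a separate LPS effect per slide, and exact permutations of genotype labels within treatment on list medians, over all splits and over those that part all numbers. The model was tested on simulated data with 50 changed genes of each size. At a log2 change of 2 it recovered 82% for the LPS contrast in ERRα+/+ cells, 84% and 76% for genotype under PBS and under LPS, 96% for the averaged genotype contrast and 60% for the difference of responses. At a log2 change of 1 these shares were 42%, 28%, 40%, 62% and 6%. In the same order 13 of 125, 6 of 110, 5 of 114, 5 of 142 and 10 of 92 calls were false. The simulated noise was independent between genes and arrays, without a shared slide effect. Far fewer genes changed than were called for LPS, so these shares need not hold for the real arrays.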

Results

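The transcriptome of bone marrow-derived macrophages was measured on 12 arrays. These cells are grown from marrow progenitors in M-CSF, the growth factor of the macrophage lineage, and LPS is a component of bacterial outer membranes that activates them through the receptor TLR4. The 4 groups were ERRα+/+ with PBS, ERRα+/+ with LPS, ERRα-/- with PBS and ERRα-/- with LPS, with 3 arrays each. Per array, 46.3% to 57.4% of probes were well above background, and 13113 genes were tested. The first principal component held 76.1% of the variance and parted LPS from PBS arrays; the second held 10.0% and parted slide 1 (replicate 1 of each group) from slide 2 (replicates 2 and 3).

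Esrra encodes ERRα, a nuclear receptor that drives genes of mitochondrial energy metabolism. Its probe read 4.54, 4.39 and 4.68 (log2 relative to the array's 75th percentile) in the ERRα+/+ PBS replicates and 2.48, 0.246 and 0.145 in the ERRα-/- PBS replicates. Under LPS it read 5.87, 6.25 and 6.36 in ERRα+/+ and 4.40, 3.92 and 3.83 in ERRα-/- cells. Averaged over both treatments, Esrra was lower in ERRα-/- cells by a log2 difference of -2.84 ± 0.36 (n = 6 arrays per genotype, adjusted p = 0.00379), in 3 of 3 replicates under each treatment. Under PBS it fell by 3.58 ± 0.51 (adjusted p = 0.0225), a call that ended without ERRα+/+ PBS replicate 2 (adjusted p = 0.0956) or replicate 3 (0.0605), and without ERRα-/- PBS replicate 2 (0.102) or replicate 3 (0.116). Under LPS the difference was -2.11 ± 0.51 and missed the threshold (adjusted p = 0.201), while within slide 2 it was -2.43 (adjusted p = 0.00137). LPS raised the Esrra signal by 3.09 ± 0.51 in ERRα-/- cells (adjusted p = 0.000698) and by 1.62 ± 0.51 in ERRα+/+ cells (adjusted p = 0.0232), and the latter call ended without any of 5 single ERRα+/+ arrays, all but LPS replicate 1, with adjusted p up to 0.0744 without ERRα+/+ LPS replicate 3. The labels do not say which part of the gene was deleted, and a probe outside the deleted part would not test the genotype.

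**Figure D1:**
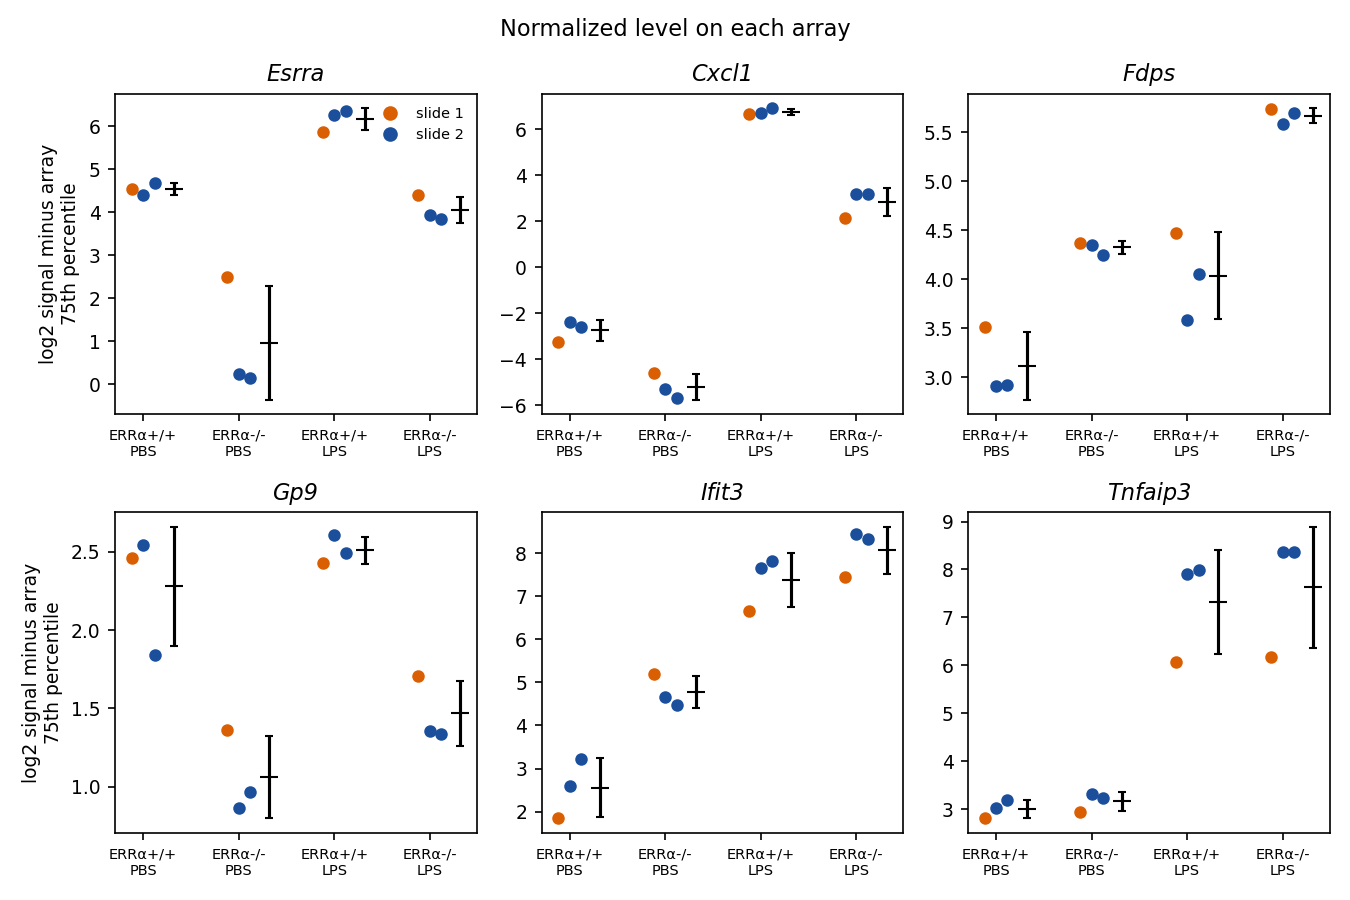
Log2 level relative to the array's 75th percentile (y axis) of Esrra, Cxcl1, Fdps, Gp9, Ifit3 and Tnfaip3 in the 4 groups (x axis). Each point is an array (orange for slide 1, blue for slide 2), dashes are group means and bars the SD of 3 arrays; Esrra lay between 4.39 and 4.68 in ERRα+/+ PBS arrays and between 0.145 and 2.48 in ERRα-/- PBS arrays.

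The LPS response of ERRα+/+ macrophages was the first comparison. Large rises were in genes of inflammation. Il6, a pyrogenic cytokine, rose at least 3148-fold (adjusted p = 1.09e-05; no PBS array was well above background), and Ptgs2, the inducible cyclooxygenase, at least 1574-fold (adjusted p = 5.67e-06). Acod1, which makes itaconate, rose by 11.59 ± 0.75, and the neutrophil-attracting chemokines Cxcl3, Cxcl2 and Cxcl1 by 10.09 ± 0.61, 10.00 ± 0.54 and 9.52 ± 0.36 (Cxcl3 and Cxcl2 above background on 1 of 3 PBS arrays). Il1b rose by 8.87 ± 0.96, Tnf by 7.58 ± 0.51, the inducible nitric oxide synthase Nos2 by 7.03 ± 0.78, and Tnfaip3, which encodes the NF-kB inhibitor A20, by 4.31 ± 0.61 (adjusted p = 0.000332). Large falls were those of Fam214a (-6.20 ± 0.42), Zfp395, Rasgrp3 (-5.67 ± 0.66), the lipid phosphatase gene Lpin1 (-5.58 ± 0.78) and the organic anion transporter gene Slco2b1 (-5.56 ± 0.47). The tested probe of Zfp395 was above background on no LPS array, so its fall is given only as at least 26.8-fold, and another of its probes, above background on 2 of 3 LPS arrays, differed by -1.37. Fam214a and Rasgrp3 were above background on 2 of 3 LPS arrays and Lpin1 on 1. All of these moved the same way in 3 of 3 replicates, which the naming rule already required of the largest rises and falls. In total 2907 genes rose and 3111 fell (limma), 8225 passed with slide as a block and 9578 within slide 2. The balance depended on the scaling: with quantile normalization 2406 rose and 3720 fell. Of 115 named genes called here, 100 stayed called without each array in turn.

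Inflammatory and interferon genes rose as groups in ERRα+/+ cells. All 36 measured interferon-stimulated genes rose, also when adjusted over the list alone, among them Rsad2 (6.98) and Gbp2 (6.70), which restrict viruses and intracellular microbes, and Ifnb1 (at least 23.4-fold), the interferon itself. The list median was 4.50 (camera adjusted p = 3.65e-21, and adjusted p = 0.275 with an estimated correlation). Of 27 NF-kB-dependent cytokines and chemokines 25 rose, 2 were not called and 26 rose adjusted over the list alone, with Ccl3 at 4.92 and Tnfsf15 at 5.55. The median was 4.96 (adjusted p = 5.44e-14, and adjusted p = 0.262 with an estimated correlation). Of 29 inflammatory effectors and receptors 24 rose, 1 fell and 4 were not called, and 25 rose and 1 fell adjusted over the list alone. The pattern receptor gene Clec4e rose by 7.30 and the mitochondrial superoxide dismutase gene Sod2 by 4.22. The median was 4.66 (adjusted p = 3.44e-11, and adjusted p = 0.262 with an estimated correlation). Of 30 genes of negative feedback on NF-kB and TLR signalling 20 rose, 2 fell and 8 were not called (21 and 2 adjusted over the list alone), with Nfkbie at 3.71 and Socs1 at 5.11. The median was 2.79 (adjusted p = 1.31e-06, and adjusted p = 0.275 with an estimated correlation).

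Proliferation and fatty acid oxidation genes fell under LPS in ERRα+/+ cells. Of 31 cell cycle genes 25 fell, 2 rose and 4 were not called, with the same numbers adjusted over the list alone. The replication helicase gene Mcm7 fell by 2.03 and the ribonucleotide reductase gene Rrm2 by 2.51. The median was -1.19 (adjusted p = 7.53e-07, and adjusted p = 0.262 with an estimated correlation). Of 25 fatty acid oxidation genes 15 fell, 2 rose and 8 were not called (16 and 2 adjusted over the list alone). Echs1 and Acadm, enzymes of β-oxidation, fell by 1.73 and 1.48, while Acsl1, which activates fatty acids, rose by 3.57. The median was -0.80 (adjusted p = 0.00167, and adjusted p = 0.262 with an estimated correlation). Of 21 glycolysis genes 9 rose, 1 fell and 11 were not called, with the same numbers adjusted over the list alone. The lactate exporter gene Slc16a3 rose by 2.45 and Pfkl by 2.06. The median was 0.64 (adjusted p = 0.0109, and adjusted p = 0.473 with an estimated correlation). Of 28 genes of cholesterol biosynthesis with LXR targets 13 rose, 2 fell and 13 were not called (14 and 3 adjusted over the list alone), with the sterol enzyme genes Hsd17b7 at 1.94 and Cyp51 at 1.40. The median was 0.48 (adjusted p = 0.0138, and adjusted p = 0.538 with an estimated correlation). Of 22 oxidative stress genes 9 rose, 3 fell and 10 were not called (9 and 4 adjusted over the list alone), led by the peroxiredoxin gene Prdx5 at 2.60 and the glutathione reductase gene Gsr at 1.94. The median was 0.92 (adjusted p = 0.00849, and adjusted p = 0.262 with an estimated correlation). Of 19 apoptosis and p53 target genes 9 rose, 1 fell and 9 were not called, with the same numbers adjusted over the list alone. Cdkn1a rose by 4.24 (its other probe differed by 1.89) and the survival gene Bcl2a1d by 3.58. The median was 0.74 (adjusted p = 0.00489, and adjusted p = 0.596 with an estimated correlation). Without ERRα+/+ LPS replicate 1 the cholesterol list (adjusted p = 0.122) and the oxidative stress list (0.0667) lost their calls, and within slide 2 the cholesterol list (0.1) and the oxidative stress list (0.0501) did.

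The other lists were not called for LPS in ERRα+/+ cells, although members moved. Of 76 oxidative phosphorylation genes 7 rose and 5 fell (2 and 0 adjusted over the list alone), with cytochrome c (Cycs) at 2.00 and a median of 0.07 (adjusted p = 0.666). Quantile normalization lowered the median response of all genes from 0.0175 to -0.143 in ERRα+/+ cells and from 0.0514 to -0.152 in ERRα-/- cells; the oxidative phosphorylation list then fell, with medians of -0.365 (adjusted p = 0.00563) and -0.406 (adjusted p = 0.0012). Of 23 tricarboxylic acid cycle genes 5 rose and 4 fell (5 and 3 adjusted over the list alone, median 0.02, adjusted p = 0.817), with Idh3g at -0.81 and Dld at 1.46. Of 29 mitochondrial ribosome genes 7 rose and 1 fell, also adjusted over the list alone (median 0.27, adjusted p = 0.0837). Of 19 genes of the ERR family with coactivators and targets 7 rose and 4 fell, also adjusted over the list alone (median 0.34, adjusted p = 0.457); the mitochondrial deacetylase gene Sirt3 fell by 2.08 and the coactivator gene Ppargc1b rose by 2.23. Of 35 autophagy and lysosome genes 7 rose and 11 fell, also adjusted over the list alone (median -0.31, adjusted p = 0.45), with the autophagy kinase gene Ulk1 at -2.21. Of 16 alternative activation genes 3 rose and 4 fell (3 and 5 adjusted over the list alone, median -0.19, adjusted p = 0.547), with Pparg at -3.08. Of 18 unfolded protein and heat stress genes 6 rose and 3 fell (7 and 3 adjusted over the list alone, median 0.50, adjusted p = 0.406), with Chac1 at 4.40. Of 10 MHC class II genes none rose and 1, the regulator Ciita, fell by 1.40 (none adjusted over the list alone by limma, median 0.29, adjusted p = 0.802); its call ended without any of 8 single arrays, with adjusted p up to 0.174 without ERRα+/+ LPS replicate 2. Of 31 genes neighbouring Esrra 13 rose and 4 fell (13 and 5 adjusted over the list alone, median 0.31, adjusted p = 0.0538).

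Markers of cell types responded in part. Of 20 macrophage identity genes 3 rose and 4 fell (3 and 3 adjusted over the list alone, median 0.05 but mean -0.08, adjusted p = 0.882), with the LPS co-receptor gene Cd14 at 2.37. Of 14 neutrophil markers 3 fell (2 adjusted over the list alone, median -0.62, adjusted p = 0.193), with myeloperoxidase (Mpo) at -2.61. Of 13 dendritic cell markers 4 rose and 1 fell (4 and 0 adjusted over the list alone, median 0.23, adjusted p = 0.45), with Zbtb46 at 6.25 (above background on 1 of 3 PBS arrays). Of 12 lymphocyte markers 1 rose and 2 fell (1 and 1 adjusted over the list alone, median -0.49, adjusted p = 0.547), with Vpreb1 at -1.98 (above background on 2 of 3 LPS arrays). Of 8 mast cell markers 1 rose and 1 fell, also adjusted over the list alone (median -0.14, adjusted p = 0.753), namely Hdc at 4.32 and Il1rl1 at -2.43 (above background on 2 of 3 LPS arrays). Of 10 erythroid and megakaryocyte markers 2 rose and 2 fell (2 and 1 adjusted over the list alone, median 0.20, adjusted p = 0.793), with Epor at -1.49. Of 16 stromal markers 2 rose and 1 fell (2 and 0 adjusted over the list alone, adjusted p = 0.742), with Pdgfrb at 5.35; their median was -0.21, but their mean, at 0.33, and the test pointed up. Of 9 osteoclast markers 3 rose and 2 fell, also adjusted over the list alone (median 0.03, adjusted p = 0.93), with Nfatc1 at -1.92.

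ERRα-/- macrophages also responded to LPS. Among the rises, Il6 rose at least 3104-fold (adjusted p = 1.09e-05), Ptgs2 at least 1872-fold, the vasoconstrictor gene Edn1 at least 853.4-fold and Cxcl3 at least 195.9-fold, since none of these was above background on a PBS array, and Acod1 rose by 9.22 ± 0.75. Il1b rose by 7.51 ± 0.96, Nos2 by 7.35 ± 0.78, Tnf by 6.92 ± 0.51 and Tnfaip3 by 4.47 ± 0.61 (adjusted p = 0.000252). Large falls were those of Fam214a (-6.57 ± 0.42), the pro-apoptotic gene Bmf (-5.93 ± 0.81), Zfp395, Zfp704 (-5.67 ± 0.92) and Rasgrp3 (-5.63 ± 0.66). The tested probe of Zfp395 was above background on no LPS array, so its fall is given as at least 21.8-fold. Another of its probes, above background on 2 of 3 LPS arrays, differed by -0.90. Each of these genes fell in 3 of 3 replicates, which the naming rule already required. Fam214a, Bmf and Rasgrp3 were above background on 2 of 3 LPS arrays and Zfp704 on 1. In total 3292 genes rose and 3320 fell (limma), 8583 passed with slide as a block and 9794 within slide 2. Here too quantile normalization moved the balance, to 2628 risen and 3946 fallen genes. Of 114 named genes called here, 98 stayed called without each array in turn.

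The same 10 lists were called in ERRα-/- cells as in ERRα+/+ cells. All 36 interferon-stimulated genes rose, also adjusted over the list alone. The median was 3.68 (adjusted p = 3.97e-17, and adjusted p = 0.301 with an estimated correlation). Of the NF-kB-dependent cytokines 26 rose, also adjusted over the list alone. The median was 5.35 (adjusted p = 9.82e-13, and adjusted p = 0.262 with an estimated correlation). Of the effectors 24 rose and 1 fell (26 and 1 adjusted over the list alone, median 3.87, adjusted p = 8.5e-10, and adjusted p = 0.262 with an estimated correlation), and of the negative feedback genes 20 rose and 3 fell (23 and 3 adjusted over the list alone, median 2.48, adjusted p = 2.65e-06, and adjusted p = 0.288 with an estimated correlation). Of the cell cycle genes 26 fell and 3 rose, also adjusted over the list alone, with the mitotic checkpoint kinase gene Bub1 at -1.73. The median was -1.39 (adjusted p = 3.17e-07, and adjusted p = 0.262 with an estimated correlation). Of the fatty acid oxidation genes 16 fell and 2 rose (16 and 3 adjusted over the list alone, median -0.71, adjusted p = 0.0048, and adjusted p = 0.275 with an estimated correlation). Of the cholesterol genes 14 rose and 2 fell, also adjusted over the list alone, with Hsd17b7 at 2.61 and Sc5d at 2.08. The median was 1.04 (adjusted p = 0.000709, and adjusted p = 0.376 with an estimated correlation). Glycolysis had 10 risen and 2 fallen members, also adjusted over the list alone. The median was 0.64 (adjusted p = 0.0212, and adjusted p = 0.518 with an estimated correlation). Of the oxidative stress genes 11 rose and 1 fell, also adjusted over the list alone (median 0.61, adjusted p = 0.0176, and adjusted p = 0.262 with an estimated correlation), a call that ended within slide 2 (adjusted p = 0.087) and without ERRα-/- LPS replicate 1 (adjusted p = 0.0688). Of the apoptosis genes 10 rose and 2 fell, also adjusted over the list alone. The median was 1.47 (adjusted p = 0.00924, and adjusted p = 0.619 with an estimated correlation).

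The LPS responses of both genotypes were close across genes, which are not independent replicates: Pearson's r was 0.956 and Spearman's rho 0.937. Both genotypes shared 2556 rises (729.8 expected by chance) and 2772 falls (787.7 expected), and no gene was called in opposite directions by limma, with no other tool run for this count. Over 4266 genes called for LPS averaged over both genotypes with a log2 response above 1, the median size was 0.094 larger in ERRα-/- cells against a median response of 1.65. The differences were 0.129, 0.0986 and 0.0671 in replicates 1 to 3, and 3 pairs cannot give an exact two-sided sign-flip p below 0.25. Without ERRα+/+ LPS replicate 1 the size difference was -0.119, and without ERRα-/- LPS replicate 1 it was 0.335. Each of these settings leaves 1 group on slide 2 alone. The LPS response was smaller on slide 1 (median ratio 0.6541 to slide 2), so both values mix slide with genotype.

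**Figure D2:**
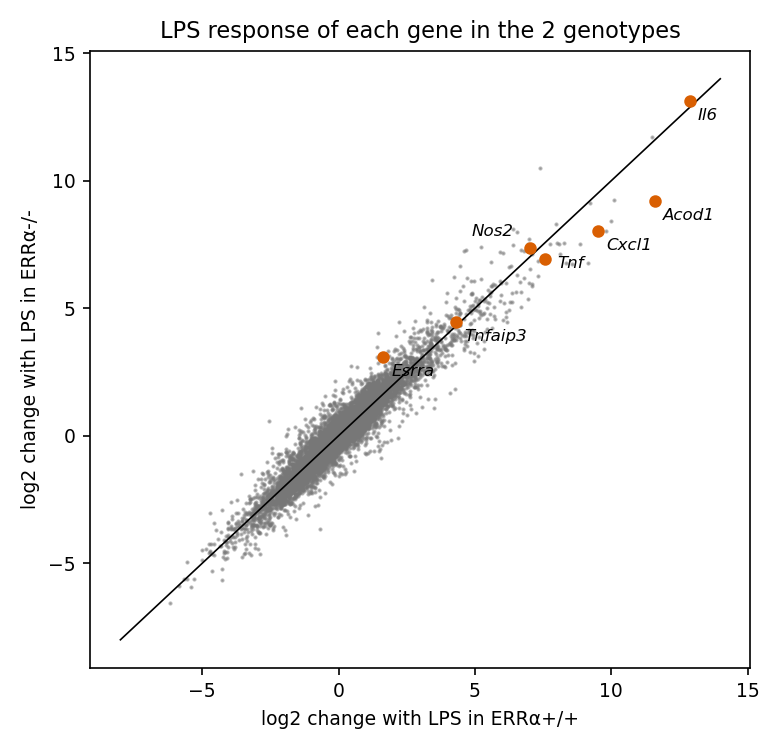
Log2 LPS response of each gene in ERRα+/+ cells (x axis) against that in ERRα-/- cells (y axis), with the line of equal response. Each point is a gene from 3 arrays per group; Pearson's r was 0.956 across genes, and Cxcl1 rose by 9.52 in ERRα+/+ and 8.03 in ERRα-/- cells, where 1 of 3 PBS arrays was above background.

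Genotype was then compared averaged over PBS and LPS, which uses all 12 arrays. The chemokine gene Cxcl1 was lower in ERRα-/- cells by a log2 difference of -3.20 ± 0.25 (n = 6 arrays per genotype, adjusted p = 0.00033). It was above background on 1 of 3 ERRα-/- PBS arrays, so the PBS part of this value rests on levels near the floor; under LPS all arrays measured it, and with normexp the average was -2.47 (adjusted p = 0.000132). The kinase gene Camk2b was lower by -2.72 ± 0.21, the fibronectin gene Fn1 by -1.56 ± 0.23 and the complement inhibitor gene Cd59a by -1.52 ± 0.10 (adjusted p = 0.000153). Higher were Syt10, a synaptotagmin gene, by 7.90 ± 0.79 (above background on 2 of 3 ERRα+/+ arrays in each treatment), Dnm1, a dynamin gene, by 6.96 ± 0.47 (adjusted p = 0.000164), the sperm protamine gene Prm1 by 3.38 ± 0.53 (above background on 1 of 3 ERRα+/+ PBS arrays), Tox4 by 2.34 ± 0.21 and Fxyd2 by 1.70 ± 0.28. Other probes of these genes did not all follow in limma. That of Dnm1 differed by 0.127 (adjusted p = 0.913), that of Tox4 by 0.233 (0.932) and that of Camk2b by -0.674 (0.21). That of Fxyd2 differed by 1.79 (0.0103). In ERRα+/+ PBS arrays the tested Dnm1 probe read -2.62, -3.60 and -2.99, while the other averaged -1.05 over all arrays. It was the higher probe on average only with the ERRα-/- arrays included. In total 52 genes were higher and 126 lower (limma). For the genes named above, all arrays of the higher genotype lay above all arrays of the lower within each treatment. This was a condition for naming them, so it is no further evidence. With slide as a block 219 were higher and 430 lower, with the replicate block 498 were called, and within slide 2 2582 were called. With the mean of replicates 2 and 3 counted as 1 sample, a setting chosen after seeing the data, limma called 0 of these genes, against 1236 at an unadjusted p under 0.05 with all arrays apart.

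The averaged count moved by over 1.5 times without ERRα+/+ PBS replicate 2 (97 genes), ERRα+/+ LPS replicate 2 (88) or replicate 3 (118), ERRα-/- PBS replicate 2 (92) or replicate 3 (81), and ERRα-/- LPS replicate 2 (107) or replicate 3 (98). Of 27 named genes called, 17 stayed called without each array, among them Esrra, Cxcl1, Cd59a, Dnm1, Fdps, Gata1 and Gp9. Tox4 lost its call without ERRα-/- PBS replicate 1 (0.33) or ERRα-/- LPS replicate 1 (0.45), where its other probe was taken, and Fxyd2 without ERRα+/+ LPS replicate 2 or ERRα-/- PBS replicate 2 or 3 (adjusted p up to 0.0559).

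Cholesterol synthesis genes were higher in ERRα-/- macrophages. Of 28 measured members 13 were called higher and none lower in the averaged contrast (15 adjusted over the list alone), 24 of 28 had positive differences, and the median was 0.87 (0.63, 1.02 and 0.89 in replicates 1 to 3). Fdps, which makes farnesyl diphosphate, was higher by 1.42 ± 0.16 (adjusted p = 0.00352), the sterol demethylase gene Cyp51 by 1.03 ± 0.12, Hsd17b7 by 0.98 ± 0.12 and the mevalonate pathway kinase gene Pmvk by 0.79 ± 0.10 (adjusted p = 0.00361 each). The camera adjusted p was 6.18e-21, and the adjusted p = 0.0566 with an estimated correlation. Under LPS alone 6 members were called (17 adjusted over the list alone), with a median of 1.15 (adjusted p = 3.2e-23, and adjusted p = 0.0557 with an estimated correlation). Under PBS alone none was called by limma at a median of 0.50 and 7 passed adjusted over the list alone (adjusted p = 1.35e-11, and adjusted p = 0.178 with an estimated correlation); with slide as a block 7 were called. Fdps differed by 1.21 ± 0.23 under PBS (adjusted p = 0.062, and 0.0178 with the replicate block).

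Megakaryocyte and stromal markers were lower in the same ERRα-/- arrays in which the cholesterol genes were higher. Of 10 erythroid and megakaryocyte markers 4 were called lower (8 adjusted over the list alone) and 1 had a positive difference, with a median of -1.08 (-0.77, -1.14 and -1.02 in replicates 1 to 3; camera adjusted p = 1.35e-11, and adjusted p = 0.0557 with an estimated correlation). These were the transcription factor gene Gata1 (-1.21 ± 0.15), the platelet glycoprotein genes Gp1bb (-1.13 ± 0.13) and Gp9 (-1.13 ± 0.15), and the platelet chemokine gene Ppbp (-1.06 ± 0.12, adjusted p = 0.00352). Of 16 stromal, fibroblast and endothelial markers 3 were called lower and 1 higher (11 and 1 adjusted over the list alone), with a median of -0.86 (-1.15, -0.80 and -0.31 in replicates 1 to 3; adjusted p = 2.68e-07, and adjusted p = 0.178 with an estimated correlation). The matrix gene Sparc was lower by -1.12 ± 0.15 and the niche chemokine gene Cxcl12 by -1.07 ± 0.19. The matrix gene Postn was above background on no ERRα-/- array and so only at least 3.05-fold lower under PBS, while the collagen cross-linking enzyme gene Lox was higher by 0.75 ± 0.14. Without single arrays the calls of Postn (3 arrays, adjusted p up to 0.0609), Cxcl12 (5 arrays, up to 0.068) and Lox (9 arrays, up to 0.0846) ended, the highest values of Postn and Cxcl12 coming without ERRα+/+ LPS replicate 2 and that of Lox without ERRα+/+ LPS replicate 3.

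Interferon-stimulated genes were higher in ERRα-/- cells as a group. All 36 had positive differences in the averaged contrast, 2 were called and 20 passed adjusted over the list alone. The median was 0.85 (1.31, 0.79 and 0.58 in replicates 1 to 3; adjusted p = 9.46e-25, and adjusted p = 0.262 with an estimated correlation). The called genes were Ifnb1 (adjusted p = 0.0249) and Ifit3 (1.45 ± 0.30, adjusted p = 0.0444), whose calls ended without 8 and 10 single arrays, with adjusted p up to 0.0887 (without ERRα-/- PBS replicate 3) and 0.131 (without ERRα-/- LPS replicate 3). Ifnb1 was above background on no PBS array of either genotype, so its averaged difference is not measured and its call is no support; under LPS it differed by 0.75 ± 0.22 (adjusted p = 0.365) and was not called. Under PBS all 36 were again positive, with a median of 1.09 (1.82, 1.07 and 0.68; adjusted p = 2.97e-32, and adjusted p = 0.262 with an estimated correlation); none was called by limma, 21 passed adjusted over the list alone and 6 passed with slide as a block. Ifit3 differed by 2.22 ± 0.42 under PBS (adjusted p = 0.062, and 0.0311 with the replicate block). Under LPS 35 of 36 were positive with a median of 0.48 (0.57, 0.50 and 0.37; adjusted p = 7.21e-08, and adjusted p = 0.562 with an estimated correlation). None was called under LPS by limma, also adjusted over the list alone, and 1 was called with slide as a block; without ERRα+/+ LPS replicate 1 the LPS median was 0.08 and its call ended (adjusted p = 0.114).

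Other lists called in the averaged contrast had smaller medians. Inflammatory effectors and receptors had a median of 0.42 with 24 of 29 positive (adjusted p = 0.000709, and adjusted p = 0.475 with an estimated correlation), and lost the call without ERRα+/+ LPS replicate 1 (adjusted p = 0.0678). Negative feedback genes had a median of 0.25 with 25 of 30 positive (adjusted p = 0.00135, and adjusted p = 0.475 with an estimated correlation), and macrophage identity genes one of 0.12 with 15 of 20 positive (adjusted p = 0.00793, and adjusted p = 0.262 with an estimated correlation), which was not called within slide 2 (0.11). Fatty acid oxidation genes, a process that ERRα is known to drive, had a median of -0.19 with 4 of 25 positive and 2 lower adjusted over the list alone (adjusted p = 0.00254, and adjusted p = 0.262 with an estimated correlation). Neutrophil markers had a median of -0.57 (0.02, -0.91 and -0.87 in replicates 1 to 3; adjusted p = 0.000709, and adjusted p = 0.377 with an estimated correlation) and mast cell markers one of -0.46 (0.21, -0.70 and -0.68; adjusted p = 0.0082, and adjusted p = 0.288 with an estimated correlation). No member of these 6 lists was called by limma without a block in the averaged contrast, and none passed adjusted over the list alone except the 2 fatty acid oxidation genes. With the replicate block Hadhb, a fatty acid oxidation gene (-0.39, adjusted p = 0.0178), and Gata2, a mast cell marker (-0.84, 0.0284), were called, and with slide as a block also Cd36, Prtn3 and Cd69.

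**Figure D3:**
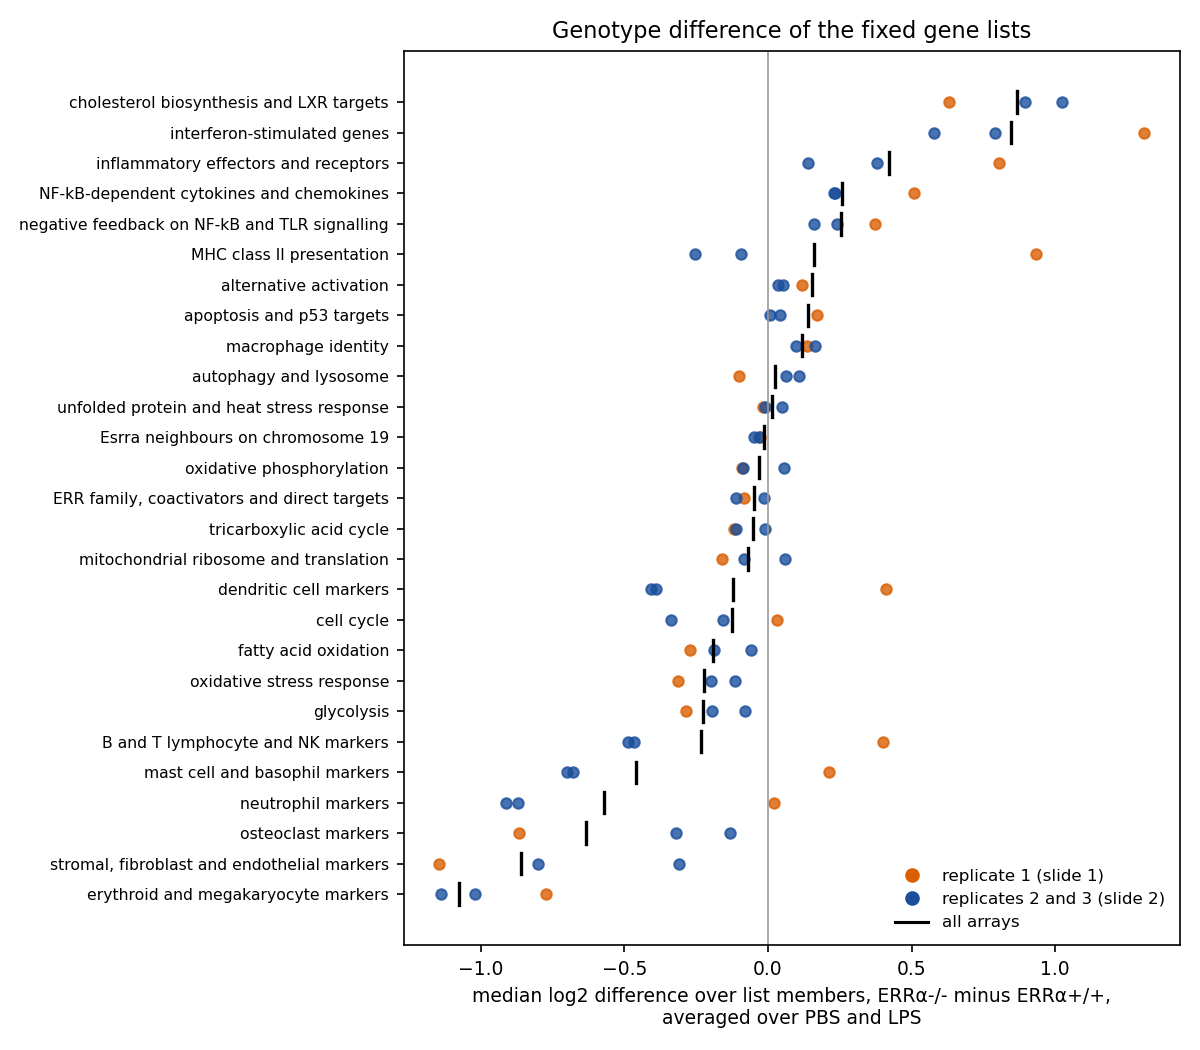
Median log2 difference between ERRα-/- and ERRα+/+ cells, averaged over PBS and LPS (x axis), for the 27 gene lists (y axis). Orange points are replicate 1, blue points replicates 2 and 3, and black lines all arrays; the cholesterol list had a median of 0.87 and the erythroid and megakaryocyte list one of -1.08.

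The remaining lists were not called in the averaged contrast. Energy metabolism lists lay near 0: oxidative phosphorylation at -0.03 (adjusted p = 0.508), the tricarboxylic acid cycle at -0.05 (0.279), mitochondrial ribosome at -0.07 (0.283) and glycolysis at -0.22 (0.0517; 1 member higher and 4 lower adjusted over the list alone). The glycolysis list passed with the replicate block (adjusted p = 0.0418). The ERR family, coactivator and target list had a median of -0.05 (adjusted p = 0.359), and Esrra was its called member. NF-kB-dependent cytokines had a median of 0.26 (adjusted p = 0.437) with Cxcl1 and Cxcl5 (-1.13 ± 0.20, adjusted p = 0.025) called lower; the Cxcl5 call ended without 7 single arrays, with adjusted p up to 0.0829 without ERRα-/- PBS replicate 3. Autophagy genes had a median of 0.02 (adjusted p = 0.45) with Uvrag higher (0.57 ± 0.11, adjusted p = 0.0334), a call that ended without 10 single arrays (up to 0.103 without ERRα-/- PBS replicate 2). Alternative activation genes had a median of 0.15 but a mean of -0.03 (adjusted p = 0.753) with Fn1 lower, cell cycle -0.13 (0.0642), MHC class II 0.16 (0.211), oxidative stress -0.22 (0.182), unfolded protein and heat stress 0.01 (0.983), apoptosis 0.14 (0.457) and the neighbours of Esrra -0.02 (0.647). Among cell type lists, dendritic cells had a median of -0.12 (adjusted p = 0.904), lymphocytes -0.23 (0.457) and osteoclasts -0.63 (0.0512), with the integrin gene Itgb3 lower by -1.02 ± 0.17 (its other probe differed by -0.36); the osteoclast list passed with the replicate block (0.0147), and Itgb3 lost its call without 4 single arrays (up to 0.0578 without ERRα-/- PBS replicate 3). Tnfaip3 differed by 0.23 ± 0.43 (adjusted p = 0.961), Tnf by 0.34 ± 0.36 (0.914), Il1b by 0.97 ± 0.68 (0.79) and Nos2 by 0.07 (0.995), while Il6 has no measured average, as no PBS array was above background.

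Under PBS, the question was how ERRα-/- macrophages differed before activation. Dnm1 was higher by 7.26 ± 0.67 (8.00, 7.22 and 6.56 in replicates 1 to 3, adjusted p = 0.0033), Syt10 by 8.13 ± 1.12 (above background on 2 of 3 ERRα+/+ arrays), Prm1 by 4.34 ± 0.74 (on 1 of 3), Tox4 by 2.20 ± 0.30 and the leukocyte receptor gene Lilra6 by 1.97 ± 0.29, of whose 3 probes the least changed differed by 0.65. Besides Esrra, the chemokine gene Cxcl14 was lower by -3.35 ± 0.53 (above background on 1 of 3 ERRα-/- arrays), Camk2b by -3.01 ± 0.29 (adjusted p = 0.0033), the endothelial transcription factor gene Sox18 by at least 2.71-fold (above background on no ERRα-/- array) and Cxcl1 by -2.46 ± 0.36 (-1.35, -2.92 and -3.10; adjusted p = 0.0232; above background on 1 of 3 ERRα-/- arrays). With normexp background correction Cxcl1 differed by -0.98 (adjusted p = 0.156), Cxcl14 by -1.18 (0.116) and Sox18 by -0.81 (0.125). These 3 calls thus ended. The values of Dnm1, Tox4 and Camk2b are those of their tested probes. Their other probes differed by 0.127, 0.233 and -0.674 in the averaged contrast. Of the megakaryocyte markers 4 were lower (6 adjusted over the list alone), with Gp1bb at -1.41 ± 0.19 (adjusted p = 0.0215) and a list median of -1.14 (adjusted p = 2.52e-11, and adjusted p = 0.0557 with an estimated correlation). Of the stromal markers 2 were lower, namely Sparc (-1.36 ± 0.21) and Cxcl12 (-1.50 ± 0.26), and 10 were lower and 1 higher adjusted over the list alone. The median was -1.08 (adjusted p = 7.17e-10, and adjusted p = 0.0977 with an estimated correlation).

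In the PBS comparison 9 genes were higher and 47 lower (limma), of 864 at an unadjusted p under 0.05. With median centring the split was 6 higher to 10 lower and with normexp 11 to 26. With slide as a block 277 were called, with the replicate block 193, and within slide 2 1206. With no filter on dim probes 5 were called, and with only the 6 PBS arrays 15. Of 17 named genes called, Dnm1 and Camk2b stayed called without each array, each by its tested probe. Gp1bb lost its call without ERRα+/+ PBS replicate 2, ERRα-/- PBS replicate 2 or replicate 3 (adjusted p up to 0.116). The count fell to 3 without ERRα-/- PBS replicate 3, 5 without ERRα+/+ PBS replicate 2, 9 without ERRα-/- PBS replicate 2, 15 without ERRα-/- PBS replicate 1 and 32 without ERRα+/+ PBS replicate 3. It was 18 without ERRα+/+ LPS replicate 3, 22 without ERRα-/- LPS replicate 3 and 30 without ERRα-/- LPS replicate 2.

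Further lists called under PBS had no member called by limma without a block; with the replicate block Hadhb (-0.50, adjusted p = 0.0481) and Gata2 (-1.34, 0.0339) passed, and with slide as a block also Mpo. Effectors had a median of 0.44 with 21 of 29 positive (adjusted p = 2.82e-05, and adjusted p = 0.377 with an estimated correlation) and negative feedback genes one of 0.25 with 22 of 30 positive (adjusted p = 0.00141, and adjusted p = 0.475 with an estimated correlation; 0.0509 without ERRα-/- PBS replicate 1). Fatty acid oxidation had a median of -0.19 with 3 of 25 positive and 1 lower adjusted over the list alone (adjusted p = 0.00265, and adjusted p = 0.262 with an estimated correlation), neutrophil markers -0.72 with 2 members lower adjusted over the list alone (adjusted p = 4.47e-06, and adjusted p = 0.262 with an estimated correlation) and mast cell markers -0.74 (adjusted p = 0.000166, and adjusted p = 0.262 with an estimated correlation). Macrophage identity had a median of 0.16 (adjusted p = 0.0416, and adjusted p = 0.275 with an estimated correlation), a call lost with the slide block (0.0745) and the replicate block (0.0709), and without replicate 1 of ERRα+/+ PBS (0.175), ERRα+/+ LPS (0.0618), ERRα-/- PBS (0.228) or ERRα-/- LPS (0.0663), or ERRα+/+ PBS replicate 2 (0.052). Osteoclast markers, at -0.81 (adjusted p = 0.0585), passed with the replicate block (0.012). Tnfaip3 differed by 0.15 ± 0.61 (adjusted p = 1), Tnf by 0.67 ± 0.51 (1), Il1b by 1.65 ± 0.96 (0.998) and Nos2 by -0.09 ± 0.78 (1), and Il6 was not well above background in either genotype.

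Under LPS, the question was how activated macrophages differed between genotypes. Cxcl1 was lower in ERRα-/- cells by -3.94 ± 0.36 (-4.55, -3.53 and -3.75 in replicates 1 to 3, adjusted p = 0.00256), Camk2b by -2.43 ± 0.29, Cd59a by -1.59 ± 0.14 (adjusted p = 0.00256), the platelet receptor gene Mpig6b by -1.14 ± 0.15 and Unc13b by -1.13 ± 0.16 (above background on 1 of 3 ERRα-/- arrays). Higher were Syt10 by 7.66 ± 1.12 (above background on 2 of 3 ERRα+/+ arrays), Dnm1 by 6.65 ± 0.67, Tox4 by 2.49 ± 0.30, Fdps by 1.63 ± 0.23 and the sterol desaturase gene Sc5d by 1.52 ± 0.21, with the cholesterol enzyme gene Pmvk at 1.26 ± 0.14 (adjusted p = 0.0079). The megakaryocyte list had a median of -0.90 with 7 of 10 members lower adjusted over the list alone and none called by limma (adjusted p = 5.69e-09, and adjusted p = 0.0734 with an estimated correlation). With the replicate block Ppbp (-1.03 ± 0.17, adjusted p = 0.0561), Gata1 (-1.03, 0.112) and Gp9 (-1.04, 0.126) passed, at 0.0262, 0.0462 and 0.0446. Tnfaip3 differed by 0.31 ± 0.61 (adjusted p = 0.995), Il1b by 0.29 (0.998), Nos2 by 0.23 (0.998), Il6 by 0.20 (0.998) and Tnf by 0.01 ± 0.51 (0.999). In total 10 genes were higher and 7 lower (limma), of 818 at an unadjusted p under 0.05. With slide as a block 212 were called (73 higher, 139 lower), with the replicate block 132 (42 higher, 90 lower) and within slide 2 2134 (1039 higher, 1095 lower). The balance of higher and lower genes thus turned with the blocks. With no filter on dim probes 6 were called, with only the 6 LPS arrays 0, and without both noisy ERRα+/+ PBS arrays, which are not part of this comparison, 2 (a setting chosen after seeing the data). Of 14 named genes called, Dnm1, Cxcl1 and Cd59a stayed called without each array. Pmvk lost its call only without ERRα+/+ LPS replicate 2 (adjusted p = 0.0722). The calls of Dnm1, Tox4 and Camk2b are those of their tested probes. Their other probes differed by 0.127, 0.233 and -0.674 in the averaged contrast. The count was 37 without ERRα-/- LPS replicate 1, 30 without ERRα+/+ PBS replicate 1, 10 without ERRα+/+ LPS replicate 1, 9 without ERRα-/- PBS replicate 2 and 7 without ERRα+/+ PBS replicate 3. It was 6 without ERRα-/- LPS replicate 2 or ERRα-/- PBS replicate 3, 5 without ERRα+/+ LPS replicate 3 or ERRα-/- LPS replicate 3, and 3 without ERRα+/+ LPS replicate 2.

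Smaller list differences under LPS had calls that changed with the setting or ended without any of several arrays. Stromal markers had a median of -0.43 with 1 lower adjusted over the list alone (adjusted p = 0.00634, and adjusted p = 0.336 with an estimated correlation), not called within slide 2 (0.214), without ERRα-/- LPS replicate 1 (0.303) or without ERRα+/+ LPS replicate 2 (0.139). Cell cycle genes had a median of -0.25 with 7 of 31 positive (adjusted p = 0.0167, and adjusted p = 0.596 with an estimated correlation), not called without ERRα+/+ LPS replicate 1 (0.119) or 3 (0.08) or ERRα-/- LPS replicate 2 (0.321) or 3 (0.0684). Fatty acid oxidation had a median of -0.16 with 6 of 25 positive (adjusted p = 0.047, and adjusted p = 0.44 with an estimated correlation), not called with the replicate block (0.0529), within slide 2 (0.139), or without ERRα+/+ LPS replicate 1 (0.458), ERRα+/+ PBS replicate 3 (0.0545) or ERRα-/- LPS replicates 1 (0.106), 2 (0.0521) or 3 (0.112). Macrophage identity had a median of 0.16 with 16 of 20 positive (adjusted p = 0.0257, and adjusted p = 0.262 with an estimated correlation), not called without ERRα+/+ LPS replicate 1 (0.0649) or 2 (0.0691) or ERRα-/- LPS replicate 1 (0.107) or 2 (0.0521). Neutrophil markers lay at -0.26 (adjusted p = 0.329) but at 0.86, -0.74 and -0.86 in replicates 1 to 3, and passed within slide 2 (5.85e-05). With the replicate block the negative feedback list (median 0.14, adjusted p = 0.0383) and the mitochondrial ribosome list (median -0.12, adjusted p = 0.0418) passed, at 0.0583 and 0.0567 without it. NF-kB-dependent cytokines had a median of 0.17, while their mean was -0.04 and the test pointed down (adjusted p = 0.844); with only probes well above background on all 12 arrays the median was 0.382 and the test pointed up (0.0234). Lymphocyte markers lay at 0.03 (adjusted p = 0.904), and at -0.590 within slide 2 (0.0229).

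Genotype differences under PBS and under LPS share no arrays, but same-numbered arrays of both treatments were correlated, so they are not independent. They had 8 called genes in common with the same sign, 63 of the 65 genes called in either had the same sign in both, and across genes r was 0.455 and rho 0.325.

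Whether ERRα changed the LPS response itself was tested as the difference of responses, ERRα-/- minus ERRα+/+. The response of Cxcl1 differed by -1.49 ± 0.50 (-3.20, -0.61 and -0.65 in replicates 1 to 3; above background on 1 of 3 ERRα-/- PBS arrays, so near the floor), that of Ifit3 by -1.53 ± 0.60, that of the bacterial lipoprotein receptor gene Tlr2 by -1.61, that of Pmvk by 0.95 ± 0.19 and that of Pparg by 0.95 ± 0.26. None passed, and no gene was called by limma, with 293 at an unadjusted p under 0.05 and a smallest adjusted p of 0.663. None was called with the slide block or the replicate block, 474 were called within slide 2, 1 was called with normexp (Cxcl1, at -2.99, adjusted p = 0.0452), and 1 was called without ERRα+/+ PBS replicate 1. Tnfaip3 differed by 0.16 ± 0.86, Tnf by -0.66 ± 0.73, Il1b by -1.35 ± 1.35, Nos2 by 0.32 ± 1.11, Acod1 by -2.38 ± 1.05 and Esrra by 1.47 ± 0.72, none of them called. Il6 was above background on no PBS array, so the difference of its responses is not measured. With array weights 1233 genes were called, and with slide by treatment, a setting chosen after seeing the data, 157. In limma with all arrays and with either block, a change called under PBS and not under LPS, or the reverse, was not shown to differ between treatments; the other settings named here did call genes.

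Among lists, the interferon-stimulated genes responded less in ERRα-/- cells by a median of -0.68 (-1.01, -0.66 and -0.29 in replicates 1 to 3) with 1 of 36 positive (adjusted p = 2.01e-10, and adjusted p = 0.473 with an estimated correlation). Their list median was higher in ERRα-/- cells under both treatments, and more so under PBS. The smaller rise is therefore not a lower level under LPS. The 36 include Ifnb1, whose response is not measured, as no PBS array was above background. Effectors differed by -0.33 (adjusted p = 0.0168, and adjusted p = 0.656 with an estimated correlation), not called within slide 2 (0.273) or without ERRα+/+ PBS replicate 1 (0.16), ERRα-/- PBS replicate 1 (0.0713), ERRα-/- LPS replicate 1 (0.746), ERRα+/+ LPS replicate 2 (0.227) or ERRα+/+ LPS replicate 3 (0.228). Cholesterol genes differed by 0.29 with 23 of 28 positive, and Pmvk passed adjusted over the list alone (adjusted p = 1.55e-06, and adjusted p = 0.262 with an estimated correlation). Stromal markers differed by 0.42 (adjusted p = 0.000739, and adjusted p = 0.262 with an estimated correlation), neutrophil markers by 0.48 (adjusted p = 0.00189, and adjusted p = 0.432 with an estimated correlation) and mast cell markers by 0.60 (adjusted p = 0.00515, and adjusted p = 0.275 with an estimated correlation). The neutrophil call ended without ERRα+/+ LPS replicate 1 (0.0667) or ERRα-/- LPS replicate 1 (0.492), and the mast cell call without ERRα-/- LPS replicate 1 (0.385). With the replicate block the NF-kB (0.042), mitochondrial ribosome (0.0418), cell cycle (0.0459) and unfolded protein (0.0383) lists passed as well. In other lists no member was called by limma, and the adjusted p lay between 0.0511 (NF-kB-dependent cytokines, median -0.50) and 0.954.

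No strain or sex check gene passed the test for genotype in limma. Averaged over treatments, Casp4, defective in some inbred strains, differed by 0.65 (adjusted p = 0.558), and the Y-linked genes Ddx3y by -0.44 (0.122), Kdm5d by -0.14 (0.931; above background on no ERRα-/- LPS array), Eif2s3y by 0.13 (0.889) and Uty by -0.01 (0.998). Ddx3y passed with slide as a block (0.0452) and with the replicate block (0.0329). Nnt, which separates C57BL6 substrains, and Xist were not measured above background.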

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

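No test in this part was chosen only after the result was seen. The difference of the LPS response between genotypes passed the preset-correlation camera test in 6 gene lists, and each is given here because an interaction term, ERRα-/- minus ERRα+/+, differed from that of other genes. The list medians were -0.3285 for inflammatory effectors and receptors, -0.6763 for interferon-stimulated genes, 0.2871 for cholesterol biosynthesis with LXR targets, 0.4811 for neutrophil markers, 0.6041 for mast cell and basophil markers and 0.4205 for stromal, fibroblast and endothelial markers. All 6 calls were lost with an estimated correlation, but that version called 0 of all 162 list tests. It missed even the LPS tests in which all measured interferon-stimulated genes rose. Its misses therefore decide nothing about these 6 lists. With the adjustment made within the contrast, 55 of 100 splits of the arrays gave at least as many called lists (real 6, highest other 17), so chance cannot be excluded for this number. For genes the real count was 0 (limma; 293 at an unadjusted p under 0.05), which each of the 100 splits must reach (highest other 1), so their number says nothing about chance.

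Probes without a gene name were outside every comparison of the report, and a signal appeared among the 10913 of them that were tested. LPS against PBS called 3425 such probes in ERRα+/+ cells (1913 higher, 1512 lower) and 3752 in ERRα-/- cells (2179 higher, 1573 lower). ERRα-/- against ERRα+/+ called 9 under PBS (6 higher, 3 lower), 11 under LPS (9 higher, 2 lower) and 27 averaged over both (16 higher, 11 lower). The difference of responses called 0 (limma), with 199 at an unadjusted p under 0.05 and no other tool run. What these probes detect is not given in the sources used here.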

How the results depend on the processing

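Settings chosen only after the result was seen were replicates 2 and 3 averaged, with and without a slide block, leaving out the 2 noisy PBS arrays, and slide by treatment. Of 4860 list values under alternatives 4475 kept their direction and their side of the threshold, 161 lost and 220 gained a call and 4 reversed; of 20785 values of named genes 19037 kept both, 852 lost and 894 gained a call and 2 reversed. The cause of each change was not tested unless the setting itself gives it (fewer arrays, fewer or more genes). With normexp the genotype counts were 37 under PBS and 112 averaged, the difference of responses called 1, and the size difference of the LPS response was 0.0598. Median centring called 16 genes under PBS and 9 under LPS; no filter on dim probes called 5, 6 and 92 (averaged), with r 0.895 between the responses. Array weights called 9626 and 10773 genes for LPS, 1553, 4006 and 3691 for genotype and 1233 for the difference. The slide block called 277, 212 and 649 genes for genotype, and slide 2 alone 9578 for LPS in ERRα+/+ cells, 1206, 2134 and 2582 for genotype and 474 for the difference. Only the groups compared gave 15 genes under PBS and 0 under LPS (limma; 818 at an unadjusted p under 0.05 with all arrays). A log2 change of at least 1 left 3828, 4233 and 114 (averaged) genes.

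The replicate block, which pairs the arrays by number, called 193 genes under PBS, 132 under LPS and 498 averaged; it changed no call of a list or of these counts beyond those given in the report, and no gene was called for the difference of responses by limma under it. Among named genes it ended no call and 40 values gained one, and it changed no other call. Among those gained for genotype under PBS were Ifit3, Fdps, Cxcl5, Cxcl9, Ifnb1, Hadhb, Ccl3, Clec9a, Gata2 and Atp6v0d2. Ifnb1 was above background on no PBS array, so its gained call is no support. Cxcl9 read only -7.33, -4.80 and -4.43 in the ERRα+/+ PBS arrays. Those gained under LPS included Ppbp, Trpt1, Gata1, Gp9, Pfkl and Rcor2. Averaged these were Aldoc, Hadhb, Ifi44, Trpt1, Slc16a3, Chil3, Ddx3y, Pfkl, Aldoa, Rcor2, Ccl3, Clec9a, Gata2, Atp6v0d2 and Dcstamp. Averaging replicates 2 and 3 left 1865 and 2280 genes for LPS and 0, 0 and 0 for genotype (limma), with Esrra at -2.58 (adjusted p = 0.326); with a slide block these were 3987 for LPS in ERRα+/+ cells and 0, 0 and 1, with Esrra at -2.58 (adjusted p = 0.164). So the genotype calls ended but for 1 gene of the averaged contrast with the slide block. Without the 2 noisy PBS arrays the counts were 2761 for LPS in ERRα+/+ cells, 33, 2 and 116 for genotype and 8 for the difference, with r 0.875. This setting leaves ERRα+/+ PBS with 1 array, from slide 1, so comparisons with that group take their spread from other groups and mix slide with group; their counts support nothing, and 4 of the 33 were among the 56 called with all arrays. Slide by treatment called 9182, 946, 1819, 2413 and 157 in the same order of contrasts. Camera with an estimated correlation called 0 of 162 list tests, against 53 with the preset one, 41 with fry and 61 with the slide block.

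Leaving out each array in turn gave 4533 to 6711 and 5151 to 7334 genes for LPS in ERRα+/+ and ERRα-/- cells, 3 to 80 under PBS, 3 to 37 under LPS, 81 to 258 averaged, 0 to 1 for the difference, 50 to 60 list tests, a size difference of -0.119 to 0.335, r of 0.935 to 0.959 and Esrra at -3.23 to -2.64. Where it left a group with 2 arrays, these were taken to vary like the other groups. Without a replicate 1 array its group lay on slide 2 alone, so those values mix slide with group. Both ends of the size difference, -0.119 and 0.335, are of this kind. Reversed were the oxidative phosphorylation list for LPS with quantile normalization (-0.365 in ERRα+/+, -0.406 in ERRα-/-), Cs (-0.0379) and Cox7a2 (-0.0284) for LPS in ERRα-/- cells with quantile normalization, and under LPS the NF-kB list with probes well above background on all 12 arrays (0.382) and the lymphocyte list within slide 2 (-0.590). Levels of probes not well above background, about as many as those above it on each array, were not measured, and changes among them would be missed.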

Other observations

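Tests chosen only after the result was seen were the share of genes with the larger response on slide 1 and their number, the dilution of other cell types and the permutation of its list members, the full set of splits that part all numbers, the other probes of top genes, the neighbourhood of Esrra, the top LPS genes as a control for neighbouring genes, and the exact permutations of list medians.

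The LPS response differed between slides as well as between treatments. Some secreted mediators rose far more on slide 2 (replicates 2 and 3), with the interleukin-1 antagonist gene Il1rn at 7.07 against 1.04 on slide 1, the anti-inflammatory cytokine gene Il10 at 3.57 against 0.24 and the monocyte chemokine gene Ccl2 at 6.04 against 2.30. Others rose more on slide 1, such as the scavenger receptor gene Marco (6.96 against 2.44) and the matrix protease gene Mmp9 (4.04 against 0.87). Tnfaip3 rose by 3.24 on slide 1 and 4.97 on slide 2 (adjusted p = 8.94e-05 for the difference). In limma 4515 genes passed for slide by treatment, and the responses on both slides had r 0.869 across genes, which are not independent replicates. These genes were named after their values were seen.

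More megakaryocyte and platelet genes than the fixed list holds were lower in ERRα-/- cells. All 23 measured members of a further list, written before their values were looked at, had negative differences averaged over PBS and LPS, and 9 were called, among them Cavin2 (-1.14), the collagen receptor gene Gp6 (-1.04) and the coagulation factor gene F5 (-1.02). Vwf and Thbs1, among the members with the highest levels in ERRα+/+ cells (3.75 and 3.60), differed by -0.80 and -0.35 and were not called. The 6 megakaryocyte members of the fixed list had a median of -1.11 with 4 called. The 7 erythroid genes had a median of -0.365 with none called by limma and no other tool run.

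The first pattern weighed is the difference in LPS response between slides. Compression of all signals on slide 1 is argued against by the spread of PBS levels over bright genes, 0.9915 of that on slide 2. The LPS response itself was smaller on slide 1, with a median ratio of 0.6541 to slide 2 over 3926 genes. Whether a weaker or compressed signal there accounts for this remains open. Of called responding genes 6.198% responded more strongly on slide 1, which met the prediction of that explanation, and the first verdict against it was withdrawn afterwards. These are the 134 genes with the larger response on slide 1. They passed a bound against the same explanation, but it was chosen after the result was seen, so they decide nothing. A different length of LPS exposure also may account for it: the late minus early difference was -0.514 (permutation p = 0.4683), and the bound written beforehand, which would have excluded this, was wrong because a p that misses the threshold excludes nothing. The slides were also separate batches, so these explanations cannot be told apart.

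The second pattern is the lower level of megakaryocyte and platelet genes in ERRα-/- cells. A higher share of macrophages that dilutes all other cell types alike may account for it and stays open. The 6 lists compared were neutrophil, dendritic cell, lymphocyte, mast cell and stromal markers, and the erythroid and megakaryocyte list itself. Their medians differed by at least 0.7082 in every replicate number. The erythroid and megakaryocyte list was the lowest in replicates 2 and 3 (-1.139 and -1.019), so it set the range there. Exchanging members between lists gave a permutation p = 0.0037, 0.158 and 0.161 in replicates 1 to 3. In replicate 1, 4 of 6 medians lay above 0, against 0 of 6 in replicates 2 and 3. A smaller number of megakaryocyte-lineage cells in the ERRα-/- cultures is consistent with the further list's median of -0.8166. Lower transcription of these genes within macrophages would give the same values and was not tested. These explanations cannot be told apart, since no cell counts are given in the sources used here.

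The third pattern is the few very large changes in ERRα-/- cells, such as Dnm1, Syt10 and Tox4. A chromosome segment carried along with Esrra is argued against for the top genes, as 0 of 10 lay among the 100 genes nearest to Esrra. Esrra itself is 1 of these 10 and could not count. The prediction written beforehand asked that none of these 100 be called, which was not met: Tm7sf2 (0.85) was called. As 1.35 were expected, this is no excess near Esrra. In limma with the replicate block the listed neighbours Trpt1 (-0.49, adjusted p = 0.0306) and Rcor2 (-0.72, adjusted p = 0.00963) were called too. The median of the neighbour list was -0.02. A segment next to Esrra stays open for these called genes. Passenger segments elsewhere may contribute: 25 pairs of called genes lay within 5 genes of each other (6 to 19 in 10000 random draws, one-sided permutation p = 0.0007), which met its prediction. As many top LPS genes gave 21 and 19 such pairs, and many of the 25 are gene families, so this count decides nothing. Probe-specific signal likewise stays open, as 2 of 4 other probes changed by less than 0.5 on the log2 scale.

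Other splits of the same arrays were counted for genes and for lists, the latter adjusted within each contrast, so that their numbers differ from those adjusted over all list tests. For the averaged genotype contrast 1 of 100 splits, the real one, gave as many as 178 genes (highest other 6), and 1 of all 32 splits that part all numbers (share 0.0312, highest other 6). This share is under 0.05 but is the smallest that 32 splits can give. It argues against chance without excluding it, and only if the replicates are separate samples. With the mean of replicates 2 and 3 as 1 sample limma called 0 genes. For its 12 called lists 15 of 100 splits gave as many (highest other 15), so chance cannot be excluded for that number. The contrasts of 3 against 3 arrays have 10 splits, too few for a share under 0.05. For genes, 1 of 10 gave as many in each, with real values of 6018, 6612, 56 and 17 and highest others of 0, 0, 0 and 3. For lists, 2, 8, 3 and 10 of 10 gave as many, with real values of 11, 10, 10 and 6 and highest others of 13, 14, 11 and 11, so regrouped arrays gave as many list calls as the real groups. Among splits that part all numbers as the real one does, 4 of 10 and 15 of 100, the highest other gene counts were 0 in the contrasts of 3 against 3 and 6 in the averaged one, and the highest list counts were 10, 12, 10, 11 and 15.

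Exact permutations of genotype labels within each treatment compared list medians of the averaged contrast. All 200 splits take no account of the slides or numbers of the arrays. Over them the cholesterol list (0.869), the erythroid and megakaryocyte list (-1.08) and the stromal list (-0.860) had an adjusted p of 0.045 by exact permutation. The interferon-stimulated genes (0.847) had 0.09. Over the 32 splits that part all numbers, the smallest p is 0.0312, and 12 of 27 lists, these 4 among them, exceeded all other splits, with an adjusted p of 0.0703 by this exact permutation. So no list passed once the numbers were kept, in a test whose smallest p leaves little room to pass. Pairing by number beyond the slide was not shown, and splits that keep only the slides were not run.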
